A study of Mus musculus with 2 samples.

How the data were processed

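Total RNA-seq libraries, made from 300 ng of RNA with spike-in RNAs added, were analysed from 2 biosamples of left cerebral cortex of female B6CASTF1/J mice aged 18 to 20 months. Per the labels both belong to 1 group, with the biological replicate numbers 1 and 2. Each library came with a gene table and 2 transcript tables. Per the text deposited with each library, the values refer to the mm10 genome and the GENCODE M21 annotation. That text gives a transcriptome alignment as the input of the gene table and of one transcript table, and the read file with an index as the input of the other, called alignment-free here. The aligner, the quantifiers and their versions are not given in the sources used here.

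Per the file headers, the alignment-based tables hold expected counts, TPM, FPKM and posterior mean TPM, and isoform shares in percent. The alignment-free tables hold estimated counts and TPM, per the file headers. The deposited expected counts are not normalized and not always whole, because reads that match several genes are shared out. The deposited TPM values have the same sum in each library, taken over genes, short-RNA entries and spike-ins. The deposited FPKM values are in constant ratio to TPM within a library. The deposited percent values give a transcript's share in its gene and were recomputed from TPM so that both kinds of table could be compared. For transcripts of 2000 bases or more, the effective length is 99.0 bases below the length in the alignment-based tables and 339.2 bases below it in the alignment-free tables, the same in both libraries, so short transcripts are counted differently in the 2 kinds of table. Reads were placed on the mm10 reference, which represents the C57BL/6J parent; the effect of CAST/EiJ variants on placement was not analysed here.

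All 55536 gene identifiers matched the GENCODE M21 annotation, from which symbols, classes and coordinates were taken. The gene tables also list 97 spike-ins and 26248 short-RNA entries that carry numbers in place of gene identifiers. Both were left out of gene tests and library sizes. Spike-ins held 0.452% of the counts in replicate 1 and 0.406% in replicate 2. Alignment-free counts were summed to genes; 86 genes had none.

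The depth was 32504959 expected counts in replicate 1 and 24899781 in replicate 2. A count of 0 allows up to 3 counts, or 0.0927 and 0.121 CPM of the counts on genes alone (32357983 and 24798683). Reads carry no molecular identifiers in these tables, so floors and counting errors cover counting error only.

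With 1 group and no contrast, no test between groups was made, and no p-value is given across genes. Levels are the mean and SD of TPM (n = 2). A gene counts as expressed at 1 TPM in both libraries. Correlations were computed across genes on log2(TPM + 1) for genes with a mean of 1 TPM. For the libraries' difference, deposited expected counts were rounded to whole numbers, genes with a mean of 10 counts or more were kept, counts were scaled with edgeR's TMM, and the log2 ratio of replicate 2 to replicate 1 was taken from log2 CPM with a prior count of 2. The coefficient of variation is the square root of edgeR's common dispersion with an intercept alone. Each gene list's median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression; a list counts as outside when it lies beyond the central 95%, and lists with fewer than 3 tested members were left out. A gene has shared reads when its expected count is fractional in either library.

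The 37 gene lists (403 entries), the 16 isoform genes, the designs and the rule for named genes were set before the data were examined. The rule takes from each list 2 to 4 of its most abundant members, with low or undetected ones where a count speaks of them, the 20 nuclear protein-coding and 10 other genes with the highest mean TPM, the 10 genes with the largest log2 ratio each way among those with a mean of 100 counts or more, and the isoform genes. Some genes that the rule names are not reported here. Examples named for a list's difference between the libraries include further members, chosen after their values were seen.

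The count steps were tested on simulated data for replicate 2 against replicate 1: 17983 genes with a coefficient of variation of 10% and 200 changed genes. The recovered value was 10.1% over unchanged genes and 13.5% with the changed genes included. All simulated 4-fold changes were recovered as over 2-fold, and 0.787% of unchanged genes passed 2-fold. Every simulated gene had the same spread, and changed genes were drawn from those with an expected 100 counts or more. The real libraries spread more, 13.9% with a trend from 8.07% to 33.45%. The simulation therefore gives neither the share of unchanged genes passing 2-fold in them nor the recovery below 100 counts. Of 200 random lists of 10 genes, 7 were called (3.50%), and a list raised by 0.50 on the log2 scale reached percentile 99.6. Alternatives covered thresholds, units, filters, scaling (TMM, DESeq2 size factors, library totals, spike-in totals), the alignment-free tables and each library alone. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.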

Results

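Total RNA was sequenced from the left cerebral cortex of female B6CASTF1/J mice, the first-generation offspring of C57BL/6J and CAST/EiJ parents, aged 18 to 20 months. The labels give 1 group of 2 libraries, numbered as biological replicates 1 and 2, and no treatment or contrast. The 2 biosamples are separate but share 1 donor entry in the labels, so whether they came from separate animals is not clear. The spread given throughout is that of these 2 libraries, which may be technical. Replicate 1 held 32504959 expected read counts and replicate 2 held 24899781. Of these, 32357983 and 24798683 lay on genes, the library sizes used here. Against them 3 counts amount to 0.0927 CPM (counts scaled to library size) in replicate 1 and 0.121 in replicate 2. This is the limit that a count of 0 allows, for counting error only. Levels are in TPM, read counts scaled by transcript length and library size, as mean ± SD of the 2 libraries (SD, n = 2) unless a library is named. They come from the gene table of each library, made from a transcriptome alignment. The alignment-free tables, made from the reads without an alignment, gave 25 of the 35 lists other than the structural and Y-linked ones a median over 1.5 times as high.

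The question a single group can answer is which cell types and pathways the tissue RNA holds. Genes of excitatory cortical neurons were abundant: all 8 members of the list reached 1 TPM in both libraries, with a median of 62.1 ± 1.24 TPM (122 TPM in the alignment-free tables). Camk2a, a synaptic kinase of excitatory neurons, stood at 1148 ± 55.8 TPM, and Slc17a7, the vesicular glutamate transporter of cortical projection neurons, at 552 ± 7.70 TPM. The 12 genes of all neurons had a median of 242 ± 3.67 TPM, led by Snap25 at 1449 ± 80.3 TPM and Syp at 814 ± 51.9 TPM, both parts of the synaptic vesicle machinery. All 8 markers of layers 2 to 4 were detected, with a median of 37.5 ± 0.318 TPM, and all 12 markers of layers 5 and 6, with a median of 12.4 ± 0.332 TPM. Rasgrf2 (106 ± 1.15 TPM) and Cux2 (97.1 ± 10.5 TPM) led the upper layers, and Bcl11b (26.4 ± 0.813 TPM) and Etv1 (25.3 ± 1.46 TPM) the deep layers.

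By list median, inhibitory neuron genes lay below the excitatory, pan-neuronal and upper-layer lists and above the deep-layer list. All 14 members reached 1 TPM in both libraries, with list medians of 27.4 and 17.5 TPM in replicates 1 and 2. That gap is set by the middle members, Vip (31.9 and 24.1 TPM) and Tac1 (22.9 and 10.9 TPM). The median log2 ratio of the members was -0.29. The neuropeptide gene Sst (174 ± 7.23 TPM) and Gad1 (174 ± 20.7 TPM), which encodes an enzyme of GABA synthesis, were the most abundant, followed by Npy (76.8 ± 9.31 TPM) and Pvalb (46.2 ± 10.6 TPM).

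Receptor subunits of both transmitter systems were measured. Of 11 AMPA and NMDA receptor genes, 10 reached 1 TPM in both libraries, with a median of 92.0 ± 0.304 TPM, led by Gria2 (224 ± 13.5 TPM) and Grin1 (184 ± 23.3 TPM); Grin3b stayed at 0.0700 and 0.130 TPM in replicates 1 and 2. Of 13 GABA-A receptor genes, 12 reached 1 TPM in both, with a median of 39.0 ± 3.97 TPM. Gabra6, a subunit known from cerebellar granule cells, had 0 reads in both libraries.

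Glial genes covered all the major types. The astrocyte list had a median of 52.7 ± 0.350 TPM with 10 of 10 members detected, led by the glutamate transporter gene Slc1a2 (672 ± 24.4 TPM) and by Aldoc (344 ± 42.3 TPM). Of the 12 oligodendrocyte genes, all were detected (median 18.4 ± 0.983 TPM), with the myelin gene Mbp at 282 ± 40.2 TPM. Oligodendrocyte precursor genes had a median of 7.29 ± 0.707 TPM and 7 of 8 members at 1 TPM or more in both libraries, led by Olig1 (29.2 ± 5.18 TPM); Enpp6 stayed below, at 0.945 ± 0.445 TPM. All 12 microglia genes were detected, with a median of 12.6 ± 2.39 TPM, among them Csf1r at 27.7 ± 1.73 TPM.

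Lists used as markers of aged or reactive glia differed in level. Disease-associated microglia, interferon response and senescence genes had medians of 0.600, 0.650 and 0.660 TPM. In the alignment-free tables these medians were 1.68, 1.38 and 0.846 TPM. In the reactive astrocyte list, 7 of 8 members reached 1 TPM in both libraries (median 6.98 ± 1.12 TPM). Gfap, the astrocyte filament gene, stood at 74.1 TPM in replicate 1 and 40.9 TPM in replicate 2. Vim had 21.9 ± 2.82 TPM and C4b 10.9 ± 4.28 TPM, while Lcn2 stayed at 0.470 ± 0.198 TPM. Of 12 genes of disease-associated microglia, 5 reached 1 TPM in both, led by Axl (14.8 ± 0.106 TPM) and Tyrobp (13.4 ± 1.01 TPM), whereas Itgax and Clec7a stayed at 0.110 ± 0.0849 and 0.110 ± 0.156 TPM and Cst7 had 0 reads. The interferon response list had 5 of 11 members at 1 TPM or more, led by Ifi27 (34.8 ± 4.99 TPM). The antigen presentation list had 5 of 8, led by B2m (55.3 ± 5.47 TPM) and H2-D1 (12.6 ± 2.17 TPM). Of 7 genes used as senescence markers, 3 reached 1 TPM in both libraries: Cdkn2d (24.5 ± 2.62 TPM), Cdkn1a (15.0 and 30.5 TPM in replicates 1 and 2) and Glb1 (10.9 and 9.83 TPM). Cdkn2a, which encodes the cell cycle inhibitor p16, had 9 reads in replicate 1 and 3 in replicate 2, or 0.380 ± 0.198 TPM. No young cortex was analysed here, so these are levels in aged tissue and not changes with age.

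Genes of vessels, meninges and blood were also detected. All 10 endothelial genes were detected (median 13.9 ± 0.0884 TPM), with Slc2a1, the glucose transporter of the blood-brain barrier, at 45.0 ± 18.2 TPM and Ly6c1 at 27.0 ± 5.36 TPM. Mural cell genes had a median of 3.83 ± 0.537 TPM, and 8 of 9 reached 1 TPM in both libraries. Vtn led at 31.3 ± 6.99 TPM, and Kcnj8 stayed at 0.810 ± 0.368 TPM. Ptgds, a prostaglandin synthase gene abundant in the leptomeninges and also expressed by oligodendrocytes, was the highest of the meningeal list, at 1321 TPM in replicate 1 and 878 TPM in replicate 2. The list as a whole had a median of 4.92 ± 0.202 TPM, with 9 of 10 members at 1 TPM or more in both libraries. Haemoglobin genes, abundant in red blood cells, were detected, with Hbb-bs at 164 ± 45.7 TPM and Hba-a1 at 159 ± 51.7 TPM; 6 of 10 blood genes reached 1 TPM in both, and the neutrophil gene S100a8 had 0 reads.

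Choroid plexus and ependymal genes were low, with medians of 0.282 ± 0.0247 and 0.335 ± 0.0495 TPM (0.581 and 1.21 TPM in the alignment-free tables) and with 3 of 8 and 2 of 7 members at 1 TPM. Ttr, the transthyretin gene and the dominant transcript of choroid plexus, had 4.76 ± 2.72 TPM, and Rarres2 led the ependymal list at 5.55 ± 0.841 TPM. Markers used for striatum were all detected (10 of 10, median 15.1 ± 1.03 TPM), led by Ppp1r1b (90.4 ± 8.12 TPM) and Penk (64.3 ± 0.651 TPM), which cortical neurons express too. The hippocampal list reached a median of 3.17 ± 0.311 TPM (7 of 10), led by Wfs1 at 58.8 ± 0.516 TPM, a gene of cortical neurons as well. The thalamic and hypothalamic list reached 2.24 ± 0.244 TPM (5 of 10), led by Slc17a6 at 13.8 ± 1.13 TPM, with Oxt and Hcrt at 0 reads. The list for olfactory bulb and cerebellum reached 0.320 ± 0.106 TPM (3 of 8), led by Calb2 at 7.62 ± 0.955 TPM, which marks cortical interneurons too.

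**Figure D1:**
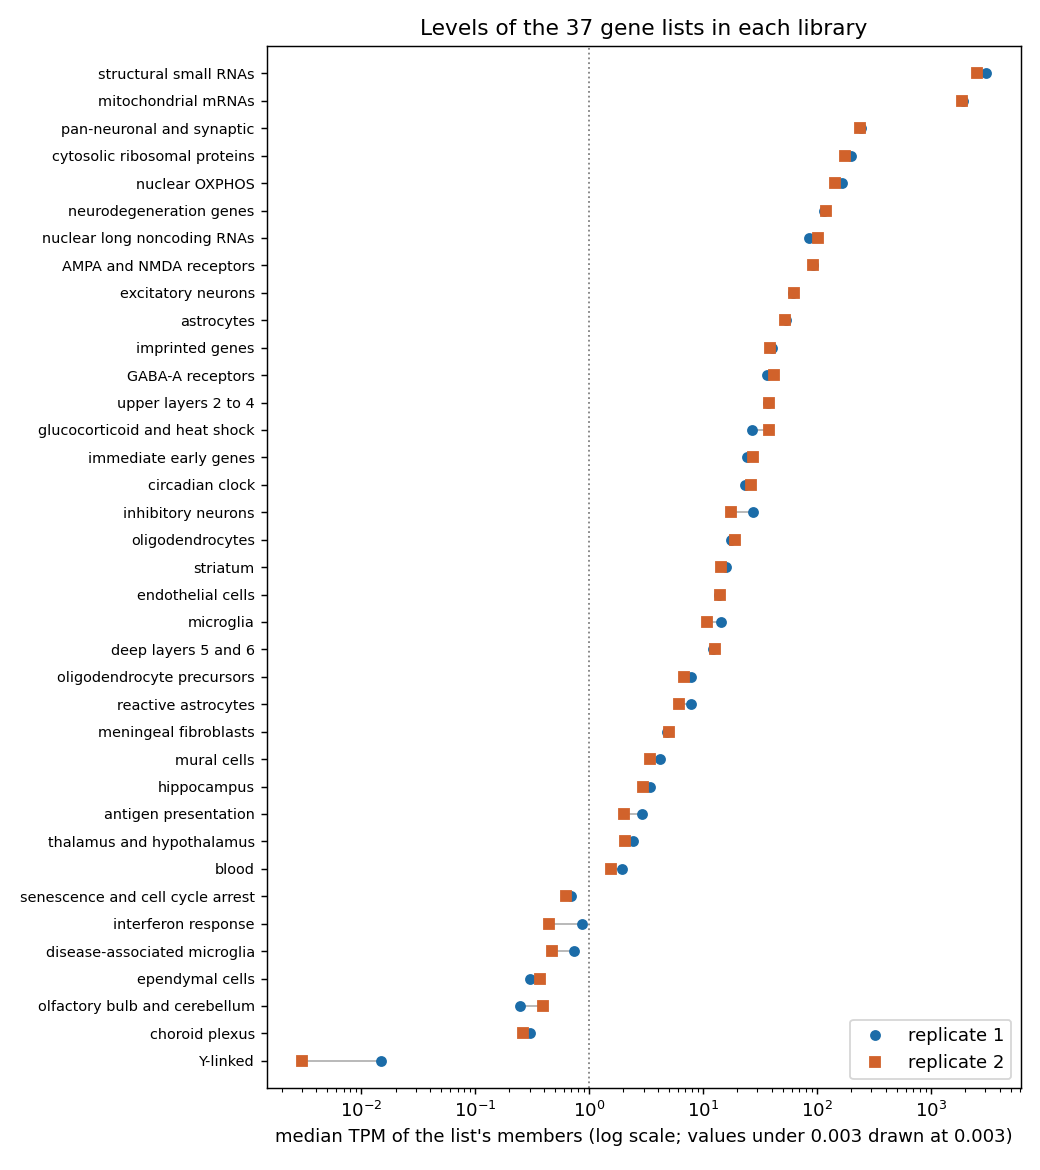
Median TPM of the members of each of the 37 gene lists (x axis, log scale) in replicate 1 (circles) and replicate 2 (squares), 1 line per list; the dotted line marks 1 TPM. Among lists of nuclear protein-coding genes the pan-neuronal list stands highest, at 242 TPM, and the Y-linked list lowest; a list median also moves when members change rank, so the libraries are compared by log2 ratios instead.

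Activity, clock and stress genes were expressed throughout. All 12 immediate early genes were detected (median 25.8 ± 2.13 TPM), led by Arc (158 ± 27.7 TPM) and Egr1 (132 ± 18.1 TPM), and all 13 clock genes (list medians of 23.6 and 26.5 TPM in replicates 1 and 2), led by Tef (102 ± 7.23 TPM) and Per1 (64.4 ± 13.1 TPM). The 12 glucocorticoid-responsive and heat shock genes had a median of 32.3 ± 7.91 TPM, with the chaperone genes Hspa8 at 969 ± 49.2 TPM and Hsp90aa1 at 424 ± 6.88 TPM. Of 23 imprinted genes, 21 reached 1 TPM in both libraries (median 39.4 ± 1.32 TPM). Gnas stood at 757 ± 26.2 TPM and Snrpn at 364 ± 10.9 TPM. Snurf had 967 ± 89.0 TPM in the gene table and 0 TPM in the alignment-free tables. Its counts, 2716 and 1783 in replicates 1 and 2, were fractional. They were far below those of Gapdh (15798 and 10940), which had a like TPM, so the level of Snurf rests on a short effective length. Magel2 (0.620 ± 0.0424 TPM) and H19 (0.145 ± 0.0495 TPM) stayed below 1 TPM. All 16 mouse orthologues of neurodegeneration genes were detected (median 117 ± 4.79 TPM), led by Apoe (745 ± 66.3 TPM), App (590 ± 8.22 TPM) and Prnp (356 ± 19.1 TPM).

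Of the 4 Y-linked genes, the gene table gave Eif2s3y, Uty and Ddx3y 1 read each in replicate 1 and Kdm5d 1 read in replicate 2, while the alignment-free tables gave them 147.8 and 211.5 estimated counts together. Xist, the RNA of the inactive X chromosome, stood at 76.5 ± 14.7 TPM.

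Among the 20 nuclear protein-coding genes with the highest TPM, after Snap25, Camk2a and Ptgds, were Gapdh (1069 ± 68.4 TPM) and Aldoa (1028.5 ± 51.5 TPM) of glycolysis, Hspa8, Snurf (by the gene table), Fth1 (965 ± 61.9 TPM), Actb (948 ± 75.5 TPM) and Eef1a1 (946 ± 67.3 TPM). Calm2 (934 ± 41.0 TPM), Cst3 (815 ± 56.9 TPM), Syp, Ckb (783 ± 77.0 TPM), Cpe (774 ± 16.9 TPM), Glul (769 ± 2.61 TPM), Gnas and Ppia (746 ± 61.3 TPM) were among them too. Nuclear genes of oxidative phosphorylation had a median of 155 ± 15.0 TPM over 15 genes, led by Atp5b (724 ± 60.7 TPM), and 16 cytosolic ribosomal protein genes a median of 187 ± 14.7 TPM, led by Rps14 (345 ± 11.2 TPM). The 13 mitochondrial mRNAs had a median of 1873 ± 24.7 TPM, with mt-Co1 at 6164 ± 450 TPM and mt-Cytb at 3170 ± 147 TPM. The value of mt-Co2, 238 ± 48.1 TPM, is uncertain. Mitochondrial genes have near-identical copies on chromosome 1, and 2 pseudogenes there, Gm28661 and Gm10925, were listed at 6883 ± 478 and 5846 ± 204 TPM.

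Short structural RNA took a large share of TPM in the gene tables, 38.8% ± 0.408, against 3.20% ± 0.272 for long noncoding genes. Rn7s1 and Rn7s2, identical copies of the 7SL RNA of the signal recognition particle between which reads were split evenly, together made up 28.0% ± 0.900 of TPM and 3.86% ± 0.0591 of counts in the gene table, while the alignment-free tables gave Rn7s1 1.27 and 0.561 TPM. The 7SK RNA gene Rn7sk made up 6.17% ± 0.178 of TPM, and Rpph1, the RNA of ribonuclease P, had 6955 ± 378 TPM. Of the 10 measured entries of the structural list, 9 reached 1 TPM in both libraries (median 2794 ± 371 TPM), and Rny3 had 0 reads. The nuclear long noncoding RNA list had a median of 93.4 ± 11.3 TPM, with 11 of 12 members at 1 TPM or more in both libraries. It was led by Malat1 at 5564 ± 1347 TPM and Meg3 at 1231 ± 425 TPM, with Tsix at 0.315 ± 0.191 TPM. By counts, nuclear protein-coding genes held 80.03% ± 0.0341 of each library, mitochondrial genes 7.48% ± 0.650, of which the ribosomal RNAs mt-Rnr1 and mt-Rnr2 held 5.79% ± 0.530, long noncoding genes 5.28% ± 0.626 and short structural RNA 5.19% ± 0.00815. The mitochondrial share may be understated, since reads placed on the chromosome 1 copies count as pseudogene reads. Gm28661 had 94758 and 64243 counts in replicates 1 and 2, and Gm10925 78202 and 55686. The 10 genes with the most counts held 15.3% ± 0.0659. Gm26917, annotated as a long noncoding gene, was among them with 654643 and 514869 counts in replicates 1 and 2. Together with Gm42418 it held 2.27% ± 0.0417 of counts, which is large beside the long noncoding share. What RNA these reads come from was not tested. In all, 14804 of 55536 annotated genes reached 1 TPM in both libraries, among them 12844 of 22015 nuclear protein-coding genes and 757 of 10155 long noncoding genes. The TPM values of the other genes are lowered by the share that structural RNA takes.

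For 16 genes with well-known isoforms, the leading transcript was compared between the libraries and between the 2 transcript tables of each library, one derived from a transcriptome alignment and the other alignment-free. The same transcript led in all 4 tables for 11 genes. Snap25-201 held 85.1% ± 0.0878 of its gene's TPM in the alignment-based tables, App-201 92.0% ± 0.234, Mapt-204 73.0% ± 2.13, Camk2a-203 62.9% ± 0.289, Gria2-202 55.3% ± 5.10, Gfap-201 91.4% ± 0.874 and Bin1-201 59.1% ± 1.76. Mbp-211 and Clu-201 led in every table, but their shares depended on the table: 65.5% ± 3.44 against 35.7% ± 4.19 for Mbp-211, and 95.9% ± 0.0938 against 52.0% ± 0.0480 for Clu-201, alignment-based against alignment-free. The tables disagreed on the leading transcript of Grin1, Meg3, Pkm and Apoe. For Pkm, a gene with 2 well-known splice forms, Pkm-202 led with 52.0% ± 0.358 in one and Pkm-201 with 46.9% ± 0.447 in the other. Bdnf was the gene whose leading transcript differed between the libraries, Bdnf-201 in replicate 1 and Bdnf-209 in replicate 2, in both kinds of table.

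Among the genes that differed between the libraries, glucocorticoid-responsive genes, a part of a fixed list set apart after the values were seen, were higher in replicate 2. Log2 ratios here are of scaled counts, and TPM, which also depends on the transcripts assigned, gives somewhat other ratios. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, had 16.1 TPM in replicate 1 and 28.9 TPM in replicate 2, a log2 ratio of 1.03, Zbtb16 had 27.2 and 58.0 TPM (1.03), Tsc22d3 33.5 and 65.4 TPM (0.97) and Plin4 1.12 and 4.18 TPM (1.84). Lower in replicate 2 were Gfap (log2 ratio -0.90), haemoglobin genes such as Hba-a1 (-0.72), the interneuron peptide gene Tac1 (-1.02) and Ttr (-1.25). The complement gene C4b stood at -1.31 with fractional counts, and its TPM was less than 2-fold apart, both in the gene table (13.9 and 7.90) and in the alignment-free tables (16.9 and 9.38). There is 1 library on each side, so these ratios have no replicate check and no p-value is given; they describe the 2 libraries, not conditions.

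Among genes with a mean of 100 counts or more, the largest ratios by the fixed rule belonged mostly to genes with fractional counts, which come from reads shared between genes, and these ratios are uncertain. Gm14440 on chromosome 2 (175275125 to 175286805, mm10) had 0 counts in replicate 1 and 402 in replicate 2, while its neighbour in the same zinc finger gene cluster, Gm14288 (175789357 to 175801093), had 543 and 0.0700. The alignment-free tables gave Gm14288 11.9 and 12.1 TPM, almost no difference. Counts were fractional too for Gm11847, Gm6361 and the entry of Zc3h11a with the highest ratio, all higher in replicate 2, and for all 10 genes that were lowest in replicate 2, Gm10359, Gm6565, Gm49388, Gm45062, Gm24497, Pagr1a, Gm5641, Nlrp5-ps and an entry of Nnt besides Gm14288. In the alignment-free tables a difference in the same direction was present for, among others, Nlrp5-ps (34.2 and 8.98 TPM), Pagr1a (14.6 and 5.76 TPM), Gm45062 (1.27 and 0.000161 TPM) and Gm11847 (0 and 2.89 TPM), and Gm10359 differed the other way (31.4 and 46.9 TPM). The genes among the 10 highest without shared reads were Hif3a, Plin4, Map3k6, Gm43174, Gm48870 and Gm43046. Hif3a, a regulator of hypoxia signalling on chromosome 7 (17031507 to 17062427), had 105 counts in replicate 1 and 426 in replicate 2, a log2 ratio of 2.37 with a counting SE of 0.16.

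A listing restricted to protein-coding genes with no shared reads was chosen after the values were seen. Of 10012 such genes with a mean of 100 counts or more, 14 differed by over 2-fold, 8 higher and 6 lower in replicate 2. Higher were Hif3a, Plin4, Map3k6 (log2 ratio 1.54), Fosb (1.32), Smim3 (1.18), Fkbp5, Zbtb16 and Galnt15 (1.00). Lower were Ttr, Lgr6 (-1.10), Gpr34 (-1.10), Gjb2 (-1.08), Tac1 and Plekho2 (-1.01). Gpr34 is a receptor of microglia, and Gjb2 a connexin of the leptomeninges and astrocytes. Gfap and Lmcd1 (-0.89) were also among the 10 lowest. The alignment-free tables gave Hif3a 2.63 and 16.3 TPM, Plin4 1.76 and 6.57 TPM, and Gfap 112 and 60.9 TPM in replicates 1 and 2.

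**Figure D2:**
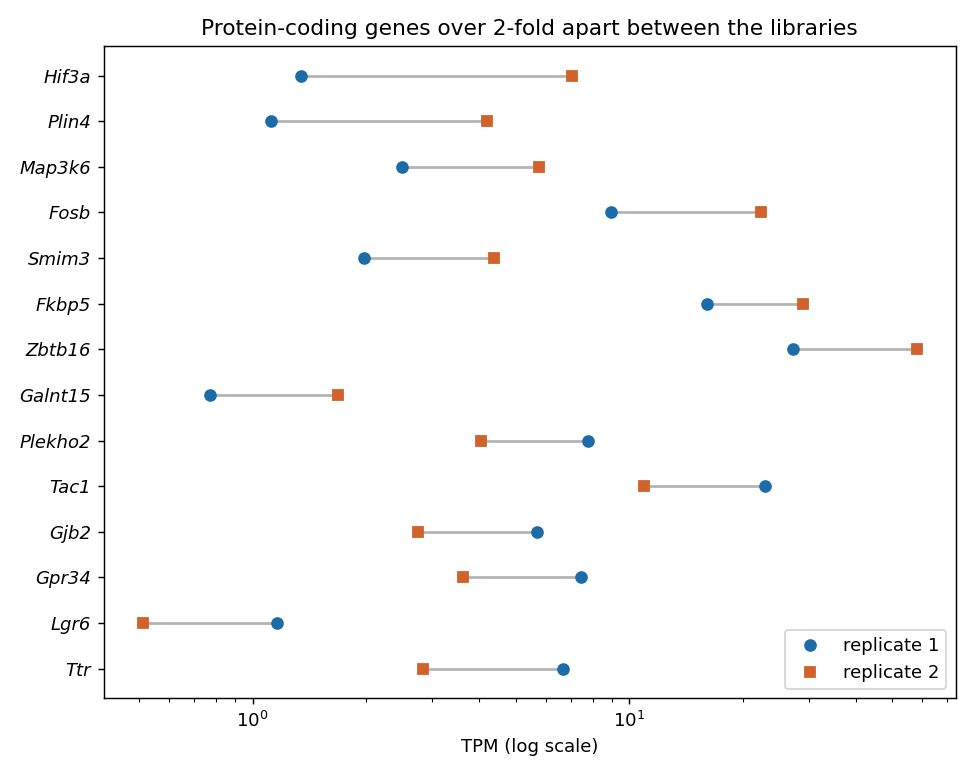
TPM (x axis, log scale) in replicate 1 (circles) and replicate 2 (squares) of the 14 protein-coding genes over 2-fold apart among those with no shared reads and a mean of 100 counts or more, ordered by log2 ratio. Hif3a has the largest ratio, 2.37 on the log2 scale, and Ttr the lowest, -1.25.

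By gene lists, interferon response, antigen presentation, blood, meningeal, oligodendrocyte, reactive astrocyte, microglia and interneuron genes were lower in replicate 2, and nuclear long noncoding RNAs were higher. Median log2 ratios were set against 10000 random lists of the same size and expression. Outside the central 95% lay 18 of 35 lists, 4 above and 14 below. Lists of genes drawn independently from all classes would give 1.75. Members of a cell type or pathway list can move together, so that number is not the chance expectation for such lists. The random range measures spread across genes, not between replicates. Of the 18, 10 lay outside in every other setting in which they were tested; the other 8 are named as such below. The lowest were the interferon response (-0.65, random range -0.23 to 0.60), blood (-0.59, range -0.20 to 0.25) and antigen presentation (-0.56, range -0.22 to 0.47). Their order depended on the setting: in the same order they were -0.29, -0.54 and -0.38 on log2(TPM + 1). In the alignment-free tables they were -0.51, -0.66 and -0.64. In these lists 0 of 9, 0 of 6 and 0 of 8 tested members lay above 0. H2-K1 stood at -0.59 and Hbb-bs at -0.60. Several interferon genes were near the floor: Ifit1 had 32 and 15 counts and Rsad2 27 and 9.

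Meningeal genes (-0.38; 2 of 10 above 0), oligodendrocyte genes (-0.33; 1 of 12), reactive astrocyte genes (-0.32; 1 of 7), inhibitory neuron genes (-0.29; 0 of 14) and microglia genes (-0.22; 0 of 12) were lower too. Mural cell genes (-0.24; 3 of 9) lay below as well, but inside in 2 of 7 other settings. Examples are Igf2 (-0.75), Mbp (-0.33), Serpina3n (-0.58), Pvalb (-0.50), Gad1 (-0.30), Vtn (-0.53) and C1qa (-0.50). General astrocyte genes (-0.09), excitatory neuron genes (-0.01) and the lists of layers 2 to 4 (-0.03) and 5 and 6 (-0.08) lay inside the random range, as did endothelial genes (-0.08), precursor genes (-0.10) and pan-neuronal genes (-0.10). The pan-neuronal list lay outside in 3 of 7 other settings and the astrocyte list in 1. Nuclear genes of oxidative phosphorylation (-0.23; 0 of 15 above 0) lay below their random range. Structural RNAs (-0.20), cytosolic ribosomal protein genes (-0.16; 1 of 16), mitochondrial mRNAs (-0.11) and the striatal list (-0.15) did so too, but lay inside in 1 of 4, 1 of 7, 2 of 6 and 6 of 7 other settings; structural RNAs were at -0.01 with a mean of 100 counts.

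Above the random range were the nuclear long noncoding RNAs (0.54; 11 of 12 above 0). Immediate early genes (0.20; 7 of 12), the glucocorticoid and heat shock list (0.14; 8 of 12) and AMPA and NMDA receptor genes (0.09; 8 of 10) also lay above, but inside in 1, 2 and 6 of 7 other settings. Meg3 stood at 0.80 and Malat1 at 0.52, with Peg13 at -0.11. Immediate early genes went both ways, with Fosb at 1.32, Npas4 at 0.55 and Egr4 at 0.51 against Ier2 at -0.81. In the stress list the 6 glucocorticoid-responsive genes all lay above 0 (median 1.00, from 0.17 for Sgk1 to 1.84 for Plin4), and the 6 heat shock genes had a median of -0.08, with Hspa8 at -0.21 and Hspa1a at -0.40; this division of the list was made after the values were seen. The clock (0.06), GABA-A receptor (-0.04), imprinted (-0.06), neurodegeneration (-0.05), hippocampal (-0.09), thalamic and hypothalamic (-0.16), disease-associated microglia (-0.17), senescence (-0.22), choroid plexus (-0.21), and olfactory bulb and cerebellum (0.20) lists lay inside. Of these, the clock and disease-associated microglia lists lay outside in 2 of 7 other settings, the choroid plexus list in 2 of 6 and the thalamic and hypothalamic list in 1 of 7. The ependymal and Y-linked lists had too few counts to be tested. Genes of the TEC class, described next, were also higher in replicate 2, with a median log2 ratio of 0.84. A link between that class and the lists was not tested. Scaling by spike-in totals raised the median of all genes by 0.16, which among the 18 lists turned the sign of the striatal list to 0.01 and of the mitochondrial list to 0.05. It brought ribosomal protein genes to -0.000612, structural RNAs to -0.04, microglia genes to -0.06, oxidative phosphorylation genes to -0.07, mural cell genes to -0.08 and inhibitory neuron genes to -0.13. Reactive astrocyte genes came to -0.16, oligodendrocyte genes to -0.17, meningeal genes to -0.22, antigen presentation to -0.40, blood to -0.43 and interferon response to -0.51. The higher lists rose further, AMPA and NMDA receptor genes to 0.25, the glucocorticoid and heat shock list to 0.30, immediate early genes to 0.36 and nuclear long noncoding RNAs to 0.70.

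**Figure D3:**
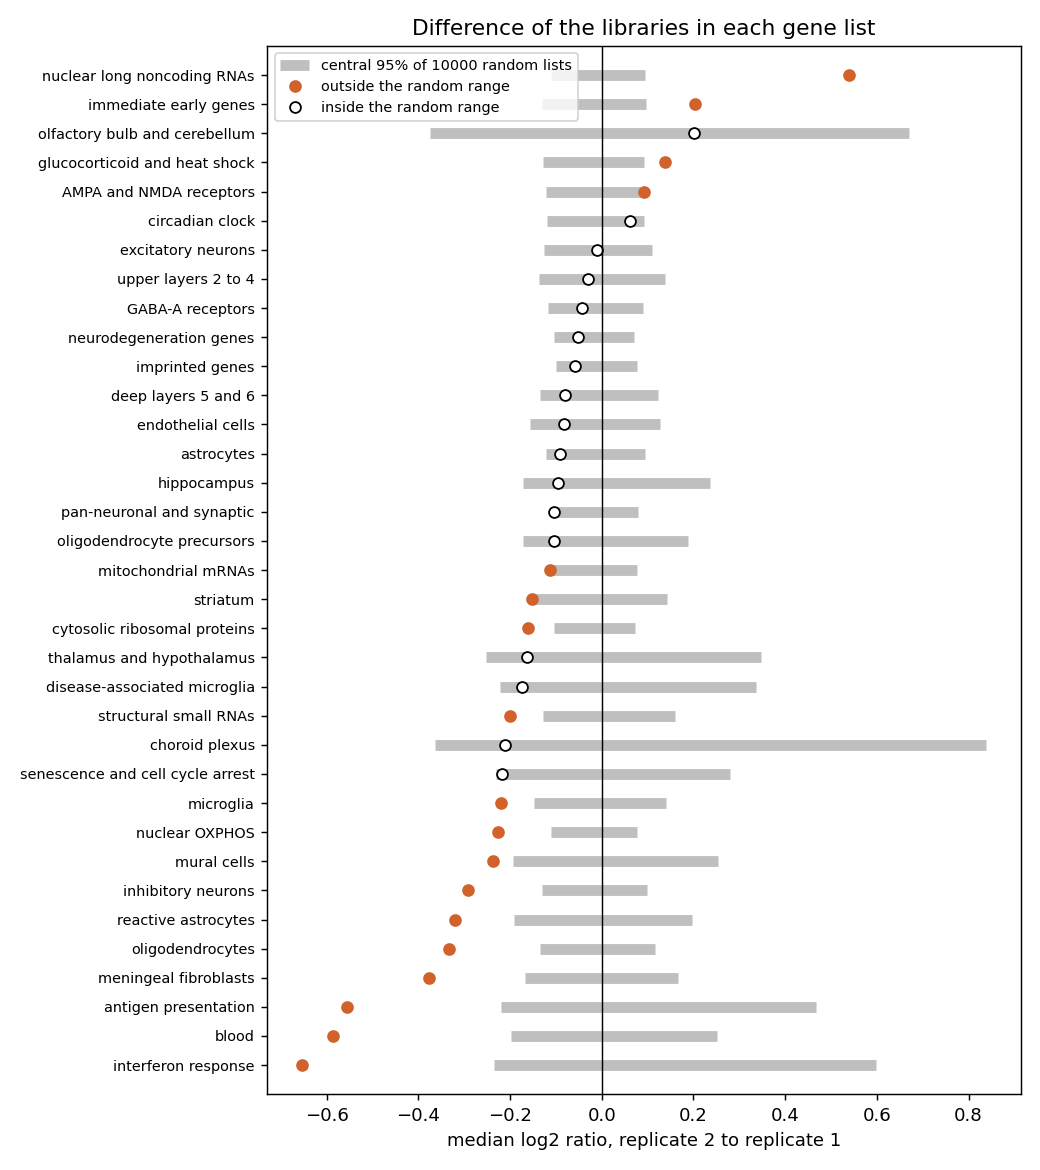
Median log2 ratio of replicate 2 to replicate 1 (x axis) for the 35 tested lists, filled where outside and open where inside the central 95% of 10000 random lists matched on size and expression (grey bars). Interferon response is lowest at -0.65 and nuclear long noncoding RNAs highest at 0.54.

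Across all genes, the class that differed most was TEC, GENCODE's class for transcribed loci whose coding status awaits experimental testing, many of them inside introns. Of 1345 TEC genes with a mean of 10 counts or more, 509 were over 2-fold apart, 507 of them higher in replicate 2, and the class had a median log2 ratio of 0.84. Long noncoding genes had a median of 0.22, with 134 of 1440 over 2-fold apart, and protein-coding genes a median of -0.03, with 225 of 14510 over 2-fold apart, 105 higher and 120 lower. In all, 997 of 18246 genes were over 2-fold apart, 813 higher and 184 lower. The TEC genes that lie on the same strand inside or across a protein-coding gene numbered 1048 and had a median of 0.91, against 0.29 for 84 genes that overlap one on the opposite strand only and 0.53 for 213 with no such overlap.

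**Figure D4:**
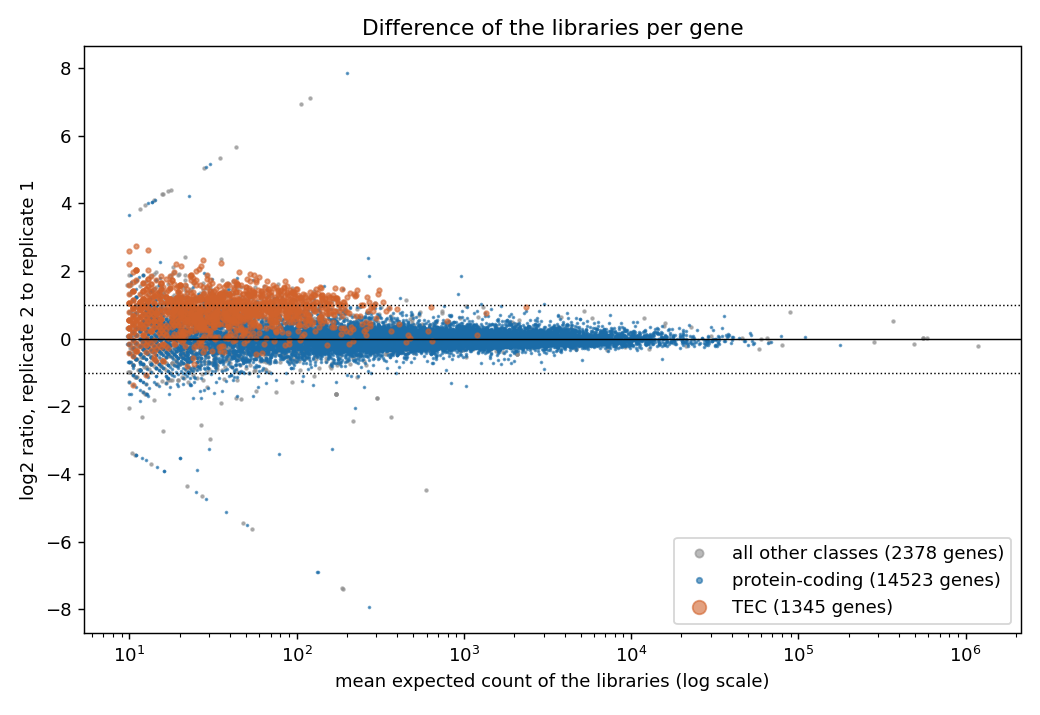
Log2 ratio of replicate 2 to replicate 1 (y axis) against the mean expected count (x axis, log scale) of each of 18246 genes; TEC genes in orange, protein-coding genes in blue, all other classes in grey, dotted lines at 2-fold. TEC genes lie mostly above 0, with a median of 0.84, and the points far from 0 in a line are genes with a count near 0 in one library.

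Across genes, Pearson's r was 0.977 and Spearman's rho 0.979 on log2(TPM + 1) across 15699 genes, which are not independent replicates. The coefficient of variation between the libraries, from edgeR's common dispersion, was 13.9% over 18246 genes; it was 9.65% over protein-coding genes. The chi-square of their counts over genes was 14.2 times its degrees of freedom, so the tables are not copies of one another.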

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

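Values in data that the report's comparisons do not use were looked for in the short-RNA entries and in the alignment-free tables. The 26248 short-RNA entries held 6 reads in replicate 1 and 6 in replicate 2, listed because their sum is above 3, and too few over so many entries to show a signal. The alignment-free tables gave the 4 Y-linked genes 147.8 estimated counts in replicate 1 and 211.5 in replicate 2, where the gene table gave 3 reads and 1 read. Most of these estimated counts lay on Kdm5d (81.9 and 106) and Uty (54.8 and 92.0), including 38.6 and 62.5 on the retained-intron transcript Uty-212. No explanation was tested for either.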

How the results depend on the processing

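The settings named below as added were chosen after the data were seen; all others were planned. Among the list medians recomputed in other settings, 204 kept their side of the random range, 21 no longer lay outside it and 11 newly lay outside. Of the 204, 9 turned sign inside the range, in 6 lists, among them the excitatory neuron and endothelial lists; no list that lay outside turned sign in these settings. Scaling by spike-in totals, which shifts all genes alike, turned the sign of 2 of the 18 lists outside. The count of expressed genes stayed within 1.5 times of 14804 in all its settings, from 10683 at 5 TPM to 21107 at 0.1 TPM, and was 16045 and 15247 in replicates 2 and 1 alone. The correlation ran from 0.946 (pseudocount 0.1) to 0.992 (no filter). The coefficient of variation of 13.9% moved to 11.1% with a mean of 100 counts, which leaves out genes with lower counts. It moved to 9.65% over protein-coding genes, which leaves out all other classes. It was 17.2% in the alignment-free tables, for which the cause was not tested, and 17.6% with spike-in totals. In an added setting it was 10.5% without TEC and long noncoding genes. In the original setting edgeR's trend of this value with expression ran from 8.07% to 33.45% over most genes. The 997 genes over 2-fold apart became 2773 with no filter beyond 1 count, 137 with a mean of 100 counts and 1502 in the alignment-free tables; the cause was not tested for the last, while the other 2 test more or fewer genes. The share that was higher in replicate 2 was 81.5%, and 91.9% in the alignment-free tables (1380 higher, 122 lower) and 70.7% with no filter; DESeq2 size factors gave 997, spike-in totals 1165 higher and 138 lower, and an added setting with no shared reads 703 higher and 91 lower. All 37 list medians moved in the alignment-free tables; those other than the structural and Y-linked ones were 1.07 to 3.62 times as high. Short structural RNA, 38.8% of TPM in the gene table, held 0.0600% and 0.0650% there, which by arithmetic raises all other TPM values; the rest of the difference was not tested. With the mean in place of the median 35 of the 37 moved, for example excitatory neurons to 333 TPM, meningeal genes to 118, blood to 48.4 and senescence genes to 8.45, since a mean follows the most abundant members. The mitochondrial share of 7.48% was 9.61% of TPM, which divides by length, and 7.02% to 7.94% in single libraries. The 18 lists outside the random range numbered 13 to 22 in the planned settings, and 14 in the added setting with random protein-coding lists. With the trend with genomic span subtracted, also added, 12 of 32 lists lay outside, 11 of them also outside in the original setting; the mural, striatal, ribosomal protein and AMPA and NMDA receptor lists then lay inside. Over all these settings 10 of the 18 stayed outside and 8 lay inside in at least 1. The 11 genes with one leading transcript were 12 in either library alone. Depth limits low genes: at a mean of 10 counts the counting error alone is large beside a 2-fold difference.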

Other observations

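Gene families chosen after the data were seen, with some members also in the fixed lists, describe the excitability and signalling genes of this tissue. Of 9 sodium channel alpha subunit genes, 6 reached 1 TPM in both libraries, led by Scn2a (125 ± 10.9 TPM), Scn8a (103 ± 9.58 TPM) and Scn1a (52.7 ± 1.85 TPM). Of 10 calcium channel alpha-1 genes, 8 reached 10 TPM in both, led by Cacna1a (96.2 ± 18.6 TPM) and Cacna1e (71.4 ± 15.6 TPM). Among the 4 HCN genes, Hcn2 was the most abundant at 61.5 ± 7.71 TPM.

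Among neuropeptide and granin genes, Cck was the most abundant at 321 ± 50.2 TPM, ahead of Sst, Vgf (163 ± 11.8 TPM) and Chgb (120 ± 8.68 TPM). Of 28 serotonin, dopamine and noradrenaline receptor genes, 20 reached 1 TPM in both, led by Adra1d (25.1 and 23.0 TPM in replicates 1 and 2) and Adrb1 (21.8 ± 0.488 TPM).

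For the explanations weighed here, the tests of low counts, of genomic DNA in parts of the classes, of genomic span, of vessel cells and of short transcripts were chosen after the results were seen, as was the division of the stress list. Those of low counts, span and short transcripts replaced tests written earlier, after the results of those were seen. Thinning replicate 1 to the depth of replicate 2 left the TEC median at 0.85, which scaling fixes whatever the cause. The span correction over all 12 stress genes changed their median from 0.14 to 0.21 and mixed in heat shock genes. Protein-coding genes of up to 340 bases numbered 2, with a ratio of 0.0108.

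TEC and long noncoding RNA genes were higher in replicate 2. For TEC genes, low counts with unequal depth are argued against, because the 194 TEC genes with a mean of 100 counts or more had a median log2 ratio of 0.89. Reads on 1466 olfactory and vomeronasal receptor genes rose by a log2 ratio of 0.50 (exact binomial 95% interval 0.36 to 0.63), below the TEC median of 0.84. If all these reads come from genomic DNA, this argues against DNA as the whole cause of that median. Receptor reads of other origin would dilute the rise, and the interval covers counting error only. DNA stays open for the 297 TEC genes with no host gene on their strand, whose median of 0.49 lies inside that interval. Of these, the 213 with no overlap had a median of 0.53. The 84 that overlap a gene on the opposite strand only had 0.29, below the interval. DNA also stays open for long noncoding genes, whose median of 0.22 lies below the interval and does not decide. The retained-intron share of reads over 5397 protein-coding genes had a median log2 ratio of 0.45, with 85.9% of genes above 0. A larger share of unspliced nuclear RNA in replicate 2 may account for the pattern. Genomic DNA would put reads in introns as well, so this share cannot tell the 2 explanations apart. No biological explanation was tested.

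Glucocorticoid-responsive genes were higher in replicate 2, with a median log2 ratio of 1.00 over the 6 members. Long protein-coding genes were higher in replicate 2 as a trend with genomic span (median 0.04 in the longest bin against -0.13 in the shortest). That trend is too small to account for a ratio of 1.00. Its subtraction could move the median only slightly whatever the cause, and left 0.98. Unspliced RNA in the 6 genes themselves was not tested. A larger share of vessel cells as the whole cause is argued against, because it needs the endothelial genes to rise by a like amount, and their median was -0.081 (SD of the 10 members 0.44) and 0.05 on log2(TPM + 1). Members went both ways, with 4 of 10 above 0, from Cldn5 at -0.68 to Ly6c1 at 0.33 and Slc2a1 at 0.81. A difference in glucocorticoid exposure between the biosamples may be a candidate explanation, and it was not tested; the labels name no difference between them.

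Structural small RNAs were abundant in the alignment-based tables and near 0 in the alignment-free ones: Rn7s1 had 140215 ± 4499 TPM in the former and 1.27 and 0.561 TPM in the latter. For reads shared between genes, 1955 genes over 1000 bases with fractional counts had a median ratio of alignment-free to alignment-based counts of 1.09. Any fractional count qualified, so many of these genes may share few reads. The test therefore cannot decide for identical copies such as Rn7s1 and Rn7s2. Transcripts shorter than the set fragment length losing their reads in the alignment-free table may be the explanation: 33 genes of other classes with no transcript over 340 bases had a median ratio of 0.0. The ratio was 0.0547 over 111 genes whose longest transcript exceeded 340 bases and reached at most 500, and 0.852 over 537 genes above that and up to 1000 bases; no biological explanation was tested.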
